A study of Mus musculus with 20 samples.

How the data were processed

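The samples were RNA pools of whole small intestine or colon from Spdef knockout and wild type mice, adult (postnatal day 30) or fetal (embryonic day 18.5), 2 to 3 littermates per pool, with 500 ng RNA amplified linearly and labelled with Cy3 or Cy5. Per the labels, each pair of pools was hybridized in both dye orders to two-colour Agilent whole mouse genome arrays, 4 to a slide. The labels give no mouse strain. Per the file headers, the authors extracted spots with Agilent Feature Extraction 9.5.3, and the mean signal, local background and processed signal of each channel are in units of intensity on a linear scale. The deposited log ratio of each scanner file is the log10 of red over green processed signal. The deposited series table holds log2 ratios of KO over wild type, with 47.8% to 72.2% of the values of an array exactly 0, as read from the table. Probe coordinates in the files are of build mm8. Gene names came from the files, updated through RefSeq accessions (23374 probes), current symbols (6733) or unique older symbols (2919) of the RefSeq gene table (GRCm38.p6, names only); 8148 probes kept the name in the file.

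From the mean signals, limma 3.58.1 under R 4.3.3 subtracted background (normexp, offset 50) and normalized each array by loess with control spots at weight 0. Control and outlier spots were left out, repeated spots of a probe averaged, and signs turned so that every ratio is KO over wild type. An array and its dye swap were averaged to 1 replicate. Fetal small intestine pairs 1 and 2, whose difference lay below the noise between arrays (r = 0.926 across genes, which are not independent replicates), were treated as repeated measurements of 1 replicate, a choice made after the data were seen; counts with the pairs separate stand among the alternatives. A probe was kept if it was well above background on all arrays of at least 1 group and genotype, and the brightest kept probe stood for a gene, which gave 17076 genes of 27573 without the filter. Replicate numbers were not used to pair pools across groups. Deviations from the group mean correlated at -0.133 to 0.152 across genes for pools of the same number and at -0.159 to 0.159 for other numbers. In groups of 2 pools the deviations mirror each other, so these values cannot show whether pools of 2 groups came from the same animals. The fit treats all pools as independent.

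All 9 replicates entered one limma fit with a term per group (5 residual degrees of freedom, empirical Bayes moderation), so that groups of 2 replicates shared a pooled estimate of the spread. Contrasts were each group, the mean of the 4, adult minus fetal, and small intestine minus colon. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors printed as ± are limma standard errors on the log2 scale. Wild type stages were compared on log2 intensities of the wild type channel after loess and Aquantile scaling between arrays. A gene whose signal was not above background in a genotype on any array of a group is given as a bound, in differences and wild type comparisons too.

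The 24 gene lists and the rule for naming genes were fixed before the data were examined. There were 9 main lists (goblet, Paneth, enteroendocrine, enterocyte, stem cell, Notch and secretory fate, ER folding, mucin glycosylation, inflammation) and 15 side lists of other cell types and tissues. They were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, adjusted over 96 tests; list tests of the 2 differences (48 tests) were added after the data were seen. Overlaps of calls used one-sided Fisher exact tests over 12 pairs of groups and directions. By the rule, named genes were Spdef and 17 panel genes in each group, of which Fcgbp was not among the genes tested; up to 6 genes higher and 6 lower with the largest change among those past the threshold with the same sign in every replicate; and up to 3 members of each main list with the smallest adjusted p. For the mean, the differences and the wild type comparisons up to 5 genes each way were taken, for the differences without the condition on replicates. Clone names, RIKEN, LOC and Gm names were counted but not named. List members outside the rule are named where 5 or fewer passed. Some genes past the threshold are not reported here.

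Alternatives were the scanner's processed signals, no background subtraction, median centring, no filter or a strict filter, the mean of all probes, slide as a random block, replicate number as a block, each group fitted alone, every array as its own observation with a dye term and the pool pair as a random block, a trended and robust prior, the series table, and leaving out each replicate. Added after the data were seen were fits with fetal small intestine pairs 1 and 2 separate, without the slide that held fetal small intestine pair 3 and fetal colon pair 1, and without genes on chromosomes X and Y. The steps were tested on simulated data with the gene spreads of these arrays, a dye effect and 200 changed genes among 17018. For adult colon, 53 of 67 genes with a log2 change of 0.5, 66 of 70 with 1 and 62 of 63 with 2 were recovered, and 8 of 189 calls were wrong; for fetal small intestine 56, 68 and 62 were recovered with 7 of 193 wrong, and for the mean of the groups 65, 70 and 63 with 12 of 210 wrong. The 1 shifted list of 96 was found and 0 of the 95 others were called (camera). The simulated genes were drawn independently of each other, whereas the estimated correlation in the data was, for example, 0.081 for goblet and 0.25 for Paneth genes. The simulation therefore does not show how often camera with the preset correlation calls unchanged lists in these data. Figures were drawn with matplotlib 3.10.9.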

Results

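Spdef encodes a transcription factor of the ETS family that is expressed in secretory cells of the intestinal epithelium. The series asked how its loss affects goblet cells, which make mucus, and Paneth cells, which release antimicrobial peptides at the crypt base. RNA from Spdef knockout (KO) and wild type mice was compared on 20 two-colour Agilent arrays, each of which held a KO pool in one channel and a wild type pool in the other. Per the labels, whole small intestines or colons were taken at postnatal day 30 (adult) or before birth (fetal), and each pool combined 2 to 3 littermates. There were 2 pairs of pools from adult small intestine (4 arrays), 3 from adult colon (6 arrays), 3 from fetal small intestine (6 arrays) and 2 from fetal colon (4 arrays), each pair hybridized in both dye orders. Fetal small intestine pairs 1 and 2 differed from each other by less than the noise between arrays (ratio of the variances 0.548, against 1.45 to 6.84 for the other pairs within a group) and were counted as 1 replicate. This left 9 replicates in all. Between 39.7% and 71.6% of the 41174 probes were well above background in a channel of an array, and 17076 genes were tested. For arrays, the number of replicates limits the precision.

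Spdef itself was lower in the KO channel on 20 of 20 arrays, with log2 ratios from -4.09 to -1.20. Its probe lies on chromosome 17, positions 27442294 to 27442353 (mm8). In adult colon Spdef fell 12.9-fold (log2 -3.69 ± 0.35, SE, n = 3, adjusted p = 0.00203). The log2 value was -2.27 ± 0.43 in adult small intestine (n = 2, adjusted p = 0.0951), -2.56 ± 0.43 in fetal small intestine (n = 2, adjusted p = 0.0673) and -2.20 ± 0.43 in fetal colon (n = 2, adjusted p = 0.154). Spdef did not pass the threshold in the contrasts of these 3 groups, whereas it did in the mean of the 4 groups (-2.68 ± 0.21, adjusted p = 0.000852). With the scanner software's own processed signals the mean log2 was -4.40 in adult small intestine, -4.22 in adult colon, -3.72 in fetal small intestine and -4.08 in fetal colon. The KO signal stayed well above background on all 20 arrays.

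**Figure D1:**
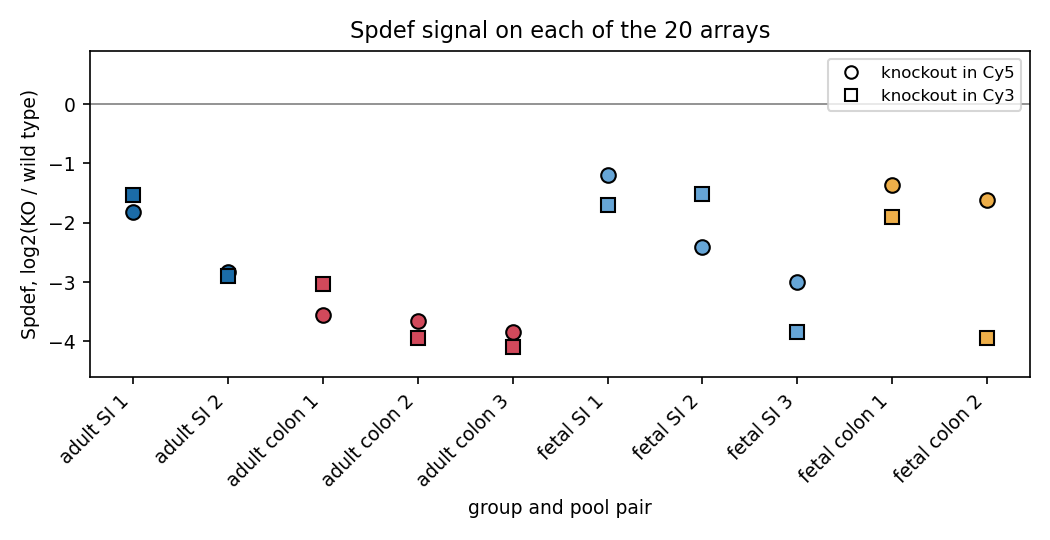
Log2 ratio of KO over wild type for Spdef on each array (y axis) by group and pool pair (x axis); each point is 1 array, circles with the KO pool in Cy5 and squares with it in Cy3. All 20 points lie between -4.09 and -1.20.

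The mean KO effect over the 4 groups addressed which genes depend on genotype across tissue and stage. The named genes lower in KO pools were led after Spdef by Creb3l4, a membrane-bound bZIP transcription factor (-2.22 ± 0.20 (adjusted p = 0.00159)), and the chemokine Ccl6 (-1.76 ± 0.16 (adjusted p = 0.00159)). Nupr1, a small stress-induced nuclear protein (-1.40 ± 0.057 (adjusted p = 3.09e-05)), and the tryptase Tpsg1 (-1.37 ± 0.053 (adjusted p = 3.09e-05)) fell as well. Higher in KO pools were the class I histocompatibility gene H2-Bl (1.94 ± 0.29 (adjusted p = 0.0162)), the aldo-keto reductase Akr1c21 (1.17 ± 0.09 (adjusted p = 0.000807)), Glo1, the glyoxalase that removes methylglyoxal (1.02 ± 0.027 (adjusted p = 3.32e-06)), Xist, the X-inactivation transcript (0.95 ± 0.19 (adjusted p = 0.0497)), and Ghrl, which encodes ghrelin (0.72 ± 0.10 (adjusted p = 0.0138)). In all, 305 genes passed, 92 higher and 213 lower. Of these, 1 gene passed as higher (Glo1) and 6 as lower (Agr2, Galnt12, Nupr1, Tpsg1, Rap1gap and Hgfac) in the contrast of each of the 4 groups. These contrasts came from the joint fit and shared one estimate of the spread per gene, so they were not independent. The probes of Glo1, Tpsg1 and H2-Bl lie 2.88, 2.34 and 8.25 Mb from that of Spdef on chromosome 17. The Akr1c21 mean rested on adult colon. That of Xist rested on fetal colon (4.02), while the value in fetal small intestine was -1.37. Both fetal values go with the sex of the pooled animals, so a dependence of Xist on genotype is not shown. The count fell to 45 without the slide that held fetal small intestine pair 3 and fetal colon pair 1. It was 167 without adult small intestine replicate 2, 186 without fetal small intestine replicate 3, 155 without adult colon replicate 1, 129 without fetal colon replicate 1, 132 without fetal colon replicate 2, and 0 with a trended, robust limma prior (2556 genes at an unadjusted p under 0.05).

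**Figure D2:**
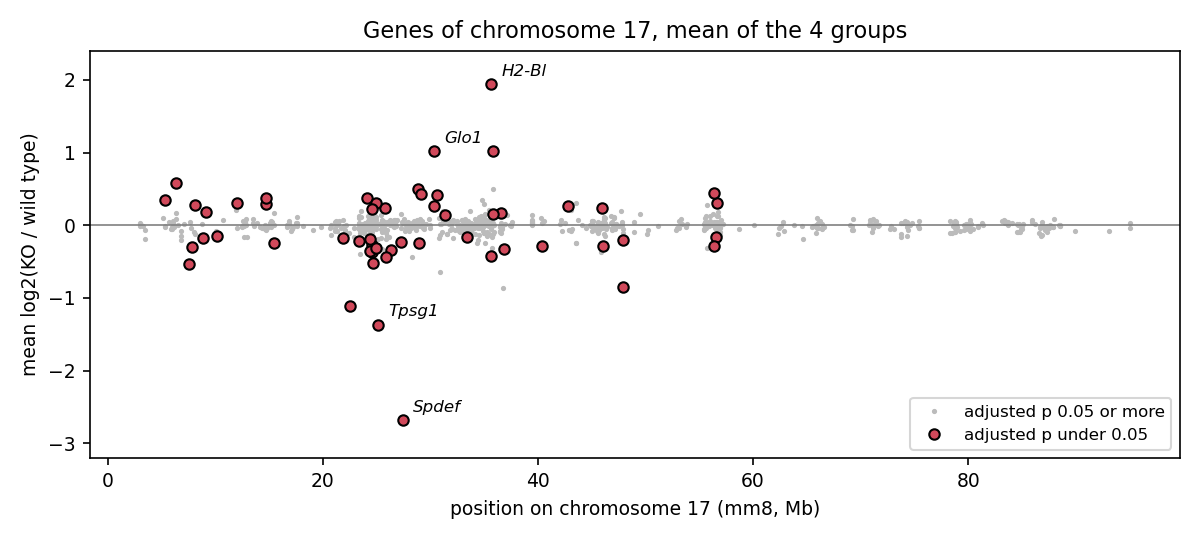
Mean log2 ratio of KO over wild type (y axis) for genes of chromosome 17 by probe position in Mb (x axis, mm8); each point is a gene, red where the adjusted p in the mean of the 4 groups is under 0.05. Genes past the threshold lie between 5.37 and 56.6 Mb on both sides of 0.

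**Figure D3:**
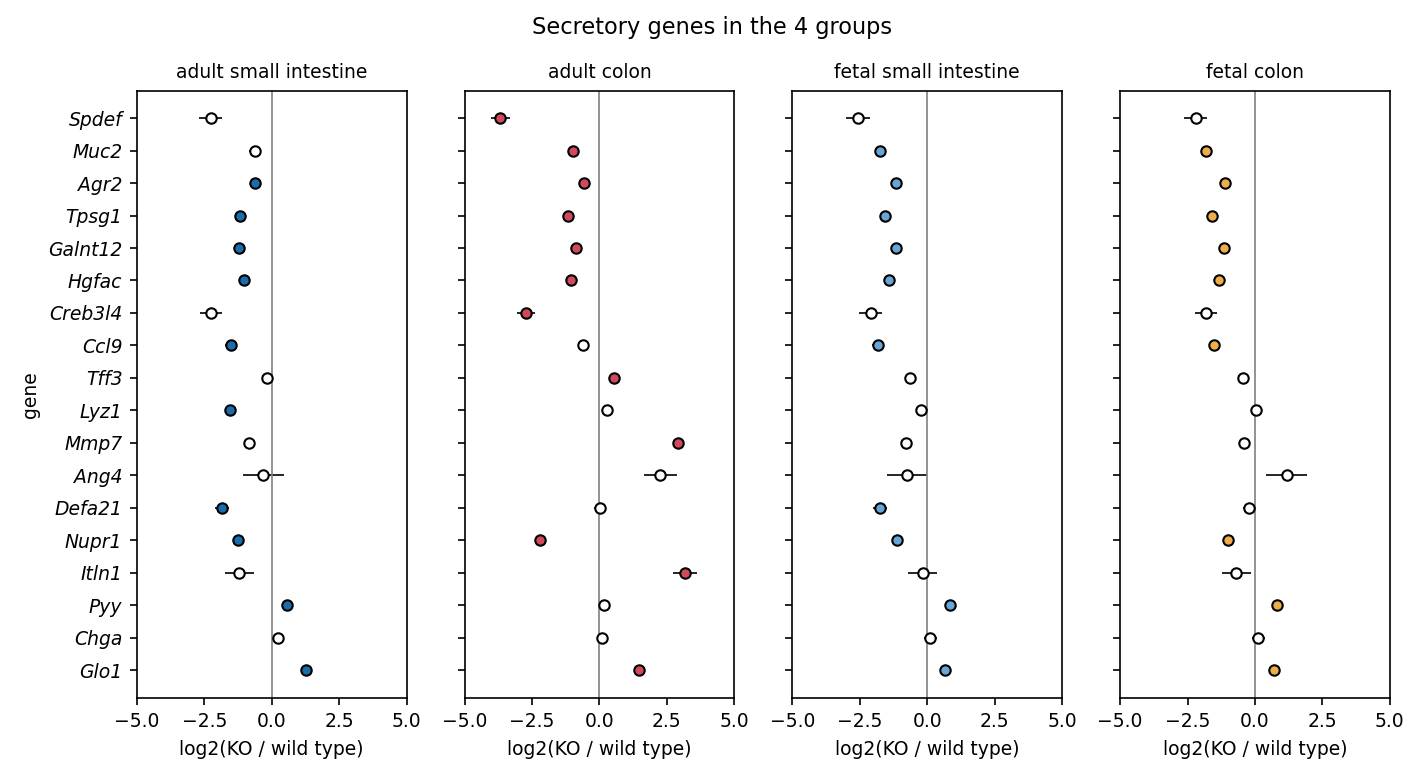
Log2 ratio of KO over wild type (x axis) for 18 genes (y axis) in the 4 groups; points are limma estimates, bars their standard errors, and filled points have an adjusted p under 0.05. Agr2, Tpsg1, Galnt12, Hgfac and Nupr1 lie below 0 and Glo1 above 0 in every panel, while Mmp7 and Itln1 rise in adult colon alone of the 4 panels.

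In adult small intestine (n = 2), Paneth cell products were among the most strongly reduced genes. The alpha-defensins, antimicrobial peptides of Paneth granules, fell, with Defa21 3.58-fold lower (log2 -1.84 ± 0.25 (adjusted p = 0.0277)), Defa20 at -1.62 ± 0.12 (adjusted p = 0.0023), Defa3 at -1.54 ± 0.23 (adjusted p = 0.0353) and Defa22 at -1.19 ± 0.069 (adjusted p = 0.000382). Lyz1, the Paneth cell lysozyme, fell 2.92-fold (-1.54 ± 0.15 (adjusted p = 0.0069)). Of 26 Paneth genes measured, 10 fell and none rose (adjusted over the list alone, 13 fell and 1 rose). Paneth cell genes had a median log2 of -0.92 (camera adjusted p = 3.82e-16; adjusted p = 0.28 with an estimated correlation). Mmp7, the protease that activates mouse alpha-defensins, had a log2 of -0.85 ± 0.16 (adjusted p = 0.0848), and Ang4, an antimicrobial angiogenin, -0.31 ± 0.76 (adjusted p = 0.93). The defensin genes are close paralogs, so single probes may read several of them.

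Goblet cell genes fell with them. Agr2, the disulfide isomerase needed for mucin folding, was lower (-0.62 ± 0.095 (adjusted p = 0.0441)), as were Galnt12, which starts mucin O-glycans (-1.21 ± 0.12 (adjusted p = 0.00737)), Tpsg1 (-1.17 ± 0.11 (adjusted p = 0.00616)), the protease Hgfac (-1.04 ± 0.11 (adjusted p = 0.00737)), the chemokine Ccl9 (-1.52 ± 0.20 (adjusted p = 0.0224)) and Nupr1 (-1.25 ± 0.12 (adjusted p = 0.00616)). The first 5 of these were the goblet list members of 43 to pass (adjusted over the list alone, 17 fell and 3 rose). Goblet cell genes had a median log2 of -0.18 (camera adjusted p = 1.56e-05; adjusted p = 0.313 with an estimated correlation). It was -0.27 without replicate 1 and -0.094 without replicate 2. Galnt12 was also the 1 of 48 mucin glycosylation genes to fall (also 1 adjusted over the list alone). Mucin glycosylation genes had a median log2 of -0.023 (camera adjusted p = 0.597; adjusted p = 0.994 with an estimated correlation). It was -0.049 without replicate 1 and 0.014 without replicate 2. The mucin Muc2 (-0.64 ± 0.20 (adjusted p = 0.262)), the trefoil factor Tff3 (-0.19 ± 0.10 (adjusted p = 0.534)), the secreted metalloprotease Clca1 (0.43 ± 0.36 (adjusted p = 0.717)) and the regulator Foxa3 (-0.37 ± 0.12 (adjusted p = 0.273)) did not pass. Neither did the secretory fate regulators Atoh1 (-0.15), Gfi1 (-0.18), Klf4 (0.15), Dll1 (-0.26) and Hes1 (-0.076), the stem cell receptor Lgr5 (-0.029), the proliferation marker Mki67 (-0.19) or the enteroendocrine granin Chga (0.23) (adjusted p of 0.545 or more).

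Genes that rose in adult small intestine were Glo1 (1.26 ± 0.057 (adjusted p = 9.94e-05)), the carbonyl reductase Cbr1 (1.08 ± 0.16 (adjusted p = 0.0421)), the enterocyte apolipoprotein Apoa4 (0.78 ± 0.087 (adjusted p = 0.00932)), the ectonucleotidase Nt5e (0.66 ± 0.096 (adjusted p = 0.0352)), the ceramidase Acer1 (0.64 ± 0.073 (adjusted p = 0.0111)) and Pyy, the hormone peptide YY (0.55 ± 0.065 (adjusted p = 0.012)). Apoa4 was the 1 of 40 enterocyte genes to pass (adjusted over the list alone, 1 rose and 2 fell). Absorptive enterocyte genes had a median log2 of -0.059 (camera adjusted p = 0.849; adjusted p = 0.994 with an estimated correlation). It was -0.12 without replicate 1 and 0.029 without replicate 2. Pyy was the 1 of 33 enteroendocrine genes to pass (adjusted over the list alone, 4 rose). Enteroendocrine cell genes had a median log2 of 0.08 (camera adjusted p = 3.45e-06; adjusted p = 0.369 with an estimated correlation). It was 0.14 without replicate 1 and 0.023 without replicate 2. The interferon-induced chemokine Cxcl9 fell (-0.39 ± 0.058 (adjusted p = 0.0359)), the 1 of 38 inflammation genes to do so (1 adjusted over the list alone). Inflammation and antimicrobial genes had a median log2 of -0.12 (camera adjusted p = 0.0357; adjusted p = 0.313 with an estimated correlation). It was -0.0091 without replicate 2 (camera adjusted p = 0.545). Prm1, known as a sperm protamine, fell on its brightest probe (-1.75 ± 0.082 (adjusted p = 9.94e-05)), but its other probe went the opposite way. In the ER folding list 0 of 55 genes passed limma's test (also 0 adjusted over the list alone). ER folding and secretion genes had a median log2 of -0.089 (camera adjusted p = 0.00145; adjusted p = 0.525 with an estimated correlation). It was -0.057 without replicate 2. Among markers of other cell types, 0 of 19 tuft cell genes passed (adjusted over the list alone, 7 rose), 1 of 13 B and plasma cell genes rose (Ighg, 1.27; 7 adjusted over the list alone) and 0 of 21 neuron and glia genes passed by limma (1 fell adjusted over the list alone). Of 18 macrophage and mast cell genes 1 fell (Lyz2, -0.90; adjusted over the list alone, 2 fell and 1 rose). Ighg and Lyz2 were chosen after their values were seen. Macrophage and mast cell genes had a median log2 of 0.019 (camera adjusted p = 0.906; adjusted p = 0.994 with an estimated correlation). Tuft cell genes had a median log2 of 0.42 (camera adjusted p = 1.31e-08; adjusted p = 0.525 with an estimated correlation). It was 0.11 without replicate 1 (camera adjusted p = 0.237). B and plasma cell genes had a median log2 of 0.29 (camera adjusted p = 1.73e-08; adjusted p = 0.313 with an estimated correlation). It was 0.14 without replicate 1 and 0.44 without replicate 2. Enteric neuron and glia genes had a median log2 of -0.065 (camera adjusted p = 0.0273; adjusted p = 0.957 with an estimated correlation). It was -0.093 without replicate 1 (camera adjusted p = 0.0876) and -0.051 without replicate 2 (camera adjusted p = 0.111). Pancreas genes, 0 of 21 past the threshold, went opposite ways in the 2 pairs, with medians of 0.87 and -3.12 over the 20 genes on no other main list. Pancreas genes had a median log2 of -1.11 (camera adjusted p = 0.0145; adjusted p = 0.957 with an estimated correlation). It was -3.00 without replicate 1 and 0.85 without replicate 2 (camera adjusted p = 5.03e-06, direction turned). In total 68 genes passed in adult small intestine, 28 higher and 40 lower. The count was 0 when the 2 pairs were fitted alone with limma (1831 at an unadjusted p under 0.05) and 20 with median centring.

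In adult colon (n = 3), KO pools lost goblet cell transcripts and gained several that Paneth cells express in the small intestine. Mmp7 rose 7.53-fold (log2 2.91 ± 0.13 (adjusted p = 3.25e-05)), the lectin Itln1 rose 9-fold (3.17 ± 0.44 (adjusted p = 0.00702)), and the angiogenins Ang2 (1.99 ± 0.51 (adjusted p = 0.0475)) and Ang6 (1.92 ± 0.49 (adjusted p = 0.0456)) rose too. Guca2b, which encodes uroguanylin, was the fifth of 26 Paneth list members to rise (1.02 ± 0.098 (adjusted p = 0.00203)), while Nupr1 (-2.21 ± 0.097 (adjusted p = 3.25e-05)) and Copz2 (-0.33) fell, Copz2 being chosen after its value was seen (adjusted over the list alone, 6 rose and 2 fell). Paneth cell genes had a median log2 of 0.15 (camera adjusted p = 0.00462; adjusted p = 0.758 with an estimated correlation). Ang4 (2.26 ± 0.62 (adjusted p = 0.0566)) and Lyz1 (0.28 ± 0.12 (adjusted p = 0.192)) did not pass, and the Ang genes are paralogs that a probe may not separate. The largest rise was that of Akr1c21, 19.6-fold (log2 4.29 ± 0.15 (adjusted p = 1.68e-05)), followed after Itln1 and Mmp7 by H2-Bl (2.59 ± 0.49 (adjusted p = 0.0194)). Itln1, H2-Bl, Ang2 and Ang6 rose least in replicate 2, by 2.17, 1.43, 0.37 and 0.63. Without replicate 3 the values were 1.25 for Ang2 (adjusted p = 0.141) and 1.13 for Ang6 (adjusted p = 0.111).

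Goblet cell genes fell in adult colon, 19 of 43, and 3 rose (adjusted over the list alone, 22 and 4). Goblet cell genes had a median log2 of -0.28 (camera adjusted p = 4.50e-07; adjusted p = 0.313 with an estimated correlation). Creb3l4 fell 6.56-fold (-2.71 ± 0.34 (adjusted p = 0.00497)) and Muc2, the main gel-forming mucin of the colon, 1.98-fold (-0.99 ± 0.16 (adjusted p = 0.0127); chromosome 7, positions 141565366 to 141565425, mm8). Tpsg1 (-1.16 ± 0.09), Hgfac (-1.05 ± 0.09), the transporter Slc12a8 (-0.93 ± 0.077), Galnt12 (-0.87 ± 0.1), Agr2 (-0.56 ± 0.077) and Foxa3 (-0.44 ± 0.098) also fell, with adjusted p from 0.000823 to 0.0327. Tff3 rose (0.56 ± 0.085 (adjusted p = 0.00998)), as did Sdf2l1 (0.31) and Capn9 (0.41), both chosen after their values were seen, and Clca1 did not pass (0.42 ± 0.30 (adjusted p = 0.4)). Of 48 mucin glycosylation genes 8 fell and 1 rose (the same adjusted over the list alone). Mucin glycosylation genes had a median log2 of -0.13 (camera adjusted p = 0.000386; adjusted p = 0.525 with an estimated correlation). Among them, besides Galnt12, were Gfpt1, which opens the hexosamine pathway (-0.58 ± 0.089 (adjusted p = 0.00996)), and the sialyltransferase St6galnac2 (-0.34 ± 0.059 (adjusted p = 0.0155)). The ER folding list moved both ways, with 4 rising and 5 falling of 55 (6 and 9 adjusted over the list alone). ER folding and secretion genes had a median log2 of -0.0056 (camera adjusted p = 0.977; adjusted p = 0.994 with an estimated correlation). It was -0.027 without replicate 1, -0.01 without replicate 2 and 0.021 without replicate 3. Herpud1, an ER degradation component (-0.41 ± 0.071 (adjusted p = 0.0146)), and the cargo receptor Lman1 (-0.27 ± 0.047 (adjusted p = 0.0145)) fell and the signal peptidase subunit Spcs3 rose (0.23 ± 0.044 (adjusted p = 0.0199)).

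Other named genes lower in adult colon were Rap1gap, which inactivates Rap1 (-1.59 ± 0.087 (adjusted p = 0.000119)), Tpd52l1 (-1.48 ± 0.08 (adjusted p = 0.000119)), and the imprinted gene Dlk1 (-1.52 ± 0.31 (adjusted p = 0.0243); -0.95 without replicate 3). The secreted lectin Reg4 fell (-0.85 ± 0.16 (adjusted p = 0.0181)), while the antimicrobial lectin Reg3b (0.62 ± 0.1 (adjusted p = 0.0116)) and the cytokine Il1b (0.76 ± 0.10 (adjusted p = 0.00671)) rose, so that 2 of 38 inflammation genes rose and 1 fell, also adjusted over the list alone. Inflammation and antimicrobial genes had a median log2 of 0.0085 (camera adjusted p = 0.734; adjusted p = 0.957 with an estimated correlation). It was 0.044 without replicate 1, 0.019 without replicate 2 and 0.0041 without replicate 3. Smaller falls were seen for Cpe, a prohormone-processing peptidase (-0.53 ± 0.12), and Cplx2 (-0.29 ± 0.067) among 33 enteroendocrine genes, of which these 2 passed (4 fell adjusted over the list alone). Enteroendocrine cell genes had a median log2 of -0.016 (camera adjusted p = 0.906; adjusted p = 0.994 with an estimated correlation). It was 0.039 without replicate 2. In the enterocyte list Maf (-0.34 ± 0.061) and the sulfate transporter Slc26a2 (-0.28 ± 0.059) fell. Absorptive enterocyte genes had a median log2 of -0.039 (camera adjusted p = 0.251; adjusted p = 0.957 with an estimated correlation). It was -0.0066 without replicate 2 and -0.094 without replicate 3 (camera adjusted p = 0.0232). In the stem cell list 2 of 26 fell (adjusted over the list alone, 3 fell and 2 rose), Msi1 (-0.37 ± 0.066) and Rgmb (-0.44 ± 0.08), the latter with its other probe in the opposite direction, as was the case for 2 of 3 other probes of Cplx2. Stem cell and Wnt target genes had a median log2 of -0.071 (camera adjusted p = 0.486; adjusted p = 0.991 with an estimated correlation). The fate regulators Atoh1 (-0.13), Gfi1 (-0.16), Klf4 (0.039), Dll1 (0.18) and Hes1 (-0.11) did not pass, nor did Lgr5 (-0.13), Mki67 (0.23) or Chga (0.096).

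Proliferation genes rose in adult colon, 23 of 31, and none fell (28 adjusted over the list alone). Proliferation genes had a median log2 of 0.33 (camera adjusted p = 1.37e-16; adjusted p = 0.348 with an estimated correlation). Log2 values of those that rose ran from 0.20 for the spindle motor Kif11 to 0.54 for the mitotic kinase Plk1, both chosen after their values were seen. Markers of the gut wall were lower, with 10 of 21 neuron and glia genes (13 adjusted over the list alone), 2 of 19 smooth muscle genes, Cald1 and Pgm5 (14 adjusted over the list alone), and 2 of 22 fibroblast genes, Postn and Mfap5 (also 2 adjusted over the list alone). Enteric neuron and glia genes had a median log2 of -0.19 (camera adjusted p = 6.51e-08; adjusted p = 0.525 with an estimated correlation). Smooth muscle genes had a median log2 of -0.32 (camera adjusted p = 8.87e-06; adjusted p = 0.62 with an estimated correlation). It was -0.20 without replicate 2. Fibroblast and matrix genes had a median log2 of -0.17 (camera adjusted p = 0.00348; adjusted p = 0.943 with an estimated correlation). Of 13 B and plasma cell genes 2 rose, Cxcr5 and Ighg (7 adjusted over the list alone). B and plasma cell genes had a median log2 of 0.31 (camera adjusted p = 0.000159; adjusted p = 0.525 with an estimated correlation). It was 0.16 without replicate 3. Among 18 macrophage and mast cell genes, Mcpt4, Mcpt1 and C1qa rose and Cma1 and Cd163 fell (adjusted over the list alone, 6 rose and 2 fell). Macrophage and mast cell genes had a median log2 of 0.10 (camera adjusted p = 0.00545; adjusted p = 0.424 with an estimated correlation). It was 0.08 without replicate 2 (camera adjusted p = 0.0509). In the T cell and NK cell list Lat rose. T cell and NK cell genes had a median log2 of 0.032 (camera adjusted p = 0.261; adjusted p = 0.962 with an estimated correlation). It was 0.11 without replicate 2 (camera adjusted p = 0.0117) and -0.044 without replicate 3. The genes named from these side lists were chosen after their values were seen. By limma 0 of 30 interferon and MHC class II genes and 0 of 13 blood and endothelium genes passed. Interferon and MHC class II genes had a median log2 of -0.26 (camera adjusted p = 0.0315; adjusted p = 0.957 with an estimated correlation). It was 0.0014 without replicate 2 (camera adjusted p = 0.898, direction turned). The medians of the 3 replicates were -0.14, -0.60 and 0.16. Blood and endothelium genes had a median log2 of -0.12 (camera adjusted p = 0.0463; adjusted p = 0.909 with an estimated correlation). It was -0.15 without replicate 1 (camera adjusted p = 0.0605) and -0.12 without replicate 3 (camera adjusted p = 0.195). Pancreas genes, 0 of 21 past the threshold, had medians of -2.32, -0.01 and -2.83 in the 3 pairs. Pancreas genes had a median log2 of -1.59 (camera adjusted p = 8.87e-06; adjusted p = 0.797 with an estimated correlation). In total 1630 genes passed in adult colon, 669 higher and 961 lower, of which 48 changed at least 2-fold. The count was 317 without adult colon replicate 1, 681 without replicate 2 and 958 without replicate 3, and 160 when the 3 pairs were fitted alone.

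In fetal small intestine as labelled (n = 2), goblet cell genes fell. Muc2 was 3.33-fold lower (log2 -1.74 ± 0.20 (adjusted p = 0.0105)) and Agr2 2.21-fold (-1.15 ± 0.095 (adjusted p = 0.00236)), together with Tpsg1 (-1.56 ± 0.11 (adjusted p = 0.00135)), Hgfac (-1.40 ± 0.11 (adjusted p = 0.00209)), Galnt12 (-1.17 ± 0.12 (adjusted p = 0.00672)), and the paralogous chemokines Ccl6 (-2.08 ± 0.33 (adjusted p = 0.0465)) and Ccl9 (-1.83 ± 0.20 (adjusted p = 0.0081)). In all 10 of 43 goblet genes fell (adjusted over the list alone, 29 fell and 1 rose). Goblet cell genes had a median log2 of -0.44 (camera adjusted p = 2.29e-34; adjusted p = 0.0682 with an estimated correlation). Over the alternatives Muc2 ran from -1.95 to -0.61, the latter for the mean of all its probes, with adjusted p up to 0.411. Tff3 (-0.65 ± 0.10 (adjusted p = 0.0516)), Foxa3 (-0.54 ± 0.12 (adjusted p = 0.181)) and Clca1 (-0.37 ± 0.36 (adjusted p = 1)) did not pass. Of 26 Paneth genes 4 fell, the alpha-defensins Defa21 (-1.76 ± 0.25 (adjusted p = 0.0316); -1.05 without replicate 1-2), Defcr4 (-0.96 ± 0.13 (adjusted p = 0.0252)) and Defa20 (-0.84, chosen after its value was seen), and Nupr1 (-1.11 ± 0.12 (adjusted p = 0.00733); 12 adjusted over the list alone). Paneth cell genes had a median log2 of -0.63 (camera adjusted p = 5.67e-16; adjusted p = 0.28 with an estimated correlation). It was -0.41 without replicate 1-2. In wild type pools Lyz1 had a log2 intensity of 10.73 and 9.64 in these pairs, against 16.56 and 16.61 in adult small intestine. Defa21 was also far lower in fetal than in adult wild type pools, as given below. The falls are therefore changes of transcripts on the list and do not show that Paneth cells were present or lost before birth. Mmp7 (-0.80 ± 0.16 (adjusted p = 0.123)), Lyz1 (-0.23 ± 0.15 (adjusted p = 0.907)) and Ang4 (-0.75 ± 0.76 (adjusted p = 1)) did not pass.

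The largest fall in fetal small intestine was that of ccdc198, a coiled-coil protein gene, 21.4-fold (log2 -4.42 ± 0.17 (adjusted p = 4.94e-05); chromosome 14, positions 48148342 to 48148401, mm8). The metal-binding protein gene Mt2 (-2.15 ± 0.27 (adjusted p = 0.0159)), Rpgrip1 (-1.78 ± 0.19 (adjusted p = 0.0081)), Reg4 (-1.44 ± 0.19 (adjusted p = 0.0225)) and the neutrophil protein gene S100a8 (-0.56 ± 0.056 (adjusted p = 0.00607)) fell as well, the last 2 being the 2 of 38 inflammation genes that passed (3 adjusted over the list alone). Inflammation and antimicrobial genes had a median log2 of -0.041 (camera adjusted p = 0.00445; adjusted p = 0.28 with an estimated correlation). It was -0.046 without replicate 3 (camera adjusted p = 0.302). Pyy rose (0.84 ± 0.065 (adjusted p = 0.00209)), again the 1 of 33 enteroendocrine genes to pass (1 adjusted over the list alone). Enteroendocrine cell genes had a median log2 of 0.15 (camera adjusted p = 1.13e-07; adjusted p = 0.313 with an estimated correlation). Galnt12 was the 1 of 48 mucin glycosylation genes to fall (2 adjusted over the list alone), and Kdelr3, a retrieval receptor for ER proteins (-0.43 ± 0.066 (adjusted p = 0.0429)), the 1 of 55 ER folding genes (2 adjusted over the list alone). Mucin glycosylation genes had a median log2 of -0.15 (camera adjusted p = 2.77e-09; adjusted p = 0.313 with an estimated correlation). It was -0.24 without replicate 1-2 and -0.063 without replicate 3 (camera adjusted p = 0.103). ER folding and secretion genes had a median log2 of -0.014 (camera adjusted p = 0.251; adjusted p = 0.957 with an estimated correlation). It was -0.056 without replicate 1-2 (camera adjusted p = 0.00206) and 0.032 without replicate 3. Atoh1 (-0.066), Gfi1 (-0.32), Klf4 (-0.19), Dll1 (0.17), Hes1 (0.04), Lgr5 (-0.20), Mki67 (0.08) and Chga (0.12) did not pass.

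Y-linked genes led the increases in fetal small intestine, and the wild type signal of Eif2s3y and Ddx3y was not above background on any array. The wild type pools carried Xist (log2 intensity 11.71 and 13.00) without Eif2s3y signal (7.13 and 6.94), while the KO pools carried both. The pools thus differed in sex make-up, and the Eif2s3y and Ddx3y differences cannot be read as effects of Spdef loss. Eif2s3y was at least 12.7-fold higher in KO pools and Ddx3y at least 4.92-fold, and they were the 2 of 4 sex-linked genes to pass (adjusted over the list alone, 3 rose and 1 fell). Sex-linked genes had a median log2 of 1.64 (camera adjusted p = 6.91e-06; adjusted p = 0.141 with an estimated correlation). With genes at their bounds the median was 1.60. The X-linked paralogs Xlr3c (1.23 ± 0.12 (adjusted p = 0.00482)) and Xlr5a (0.96 ± 0.15 (adjusted p = 0.0422); 0.58 without replicate 3, adjusted p = 0.101), the RNA-binding protein gene Rbm45 (1.19 ± 0.063 (adjusted p = 0.00044)) and Rrp7a (1.91 ± 0.19 (adjusted p = 0.00482)) also rose, the last with its other probe in the opposite direction. Of 18 macrophage and mast cell genes 1 rose (Cpa3, 0.50, chosen after its value was seen; also 1 adjusted over the list alone), and 0 of 31 proliferation genes passed, also adjusted over the list alone. Macrophage and mast cell genes had a median log2 of 0.077 (camera adjusted p = 0.0002; adjusted p = 0.313 with an estimated correlation). Proliferation genes had a median log2 of -0.079 (camera adjusted p = 0.0349; adjusted p = 0.957 with an estimated correlation). It was 0.094 without replicate 1-2 (camera adjusted p = 0.0226, direction turned) and -0.22 without replicate 3. In total 75 genes passed, 22 higher and 53 lower. Fetal small intestine pair 3 carried the tissue profile of colon in both channels (tissue score 1.61, against -2.20 for pair 1-2), so the group as labelled averages different profiles. The count was 31 without replicate 1-2, 31 without replicate 3, 28 when the group was fitted alone and 14 without the slide of pair 3.

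In fetal colon as labelled (n = 2), Muc2 fell 3.47-fold (log2 -1.80 ± 0.20 (adjusted p = 0.0135)) and Agr2 2.19-fold (-1.13 ± 0.095 (adjusted p = 0.00388)). The Muc2 value ran from -2.18 to -0.58 over the alternatives, the latter for the mean of all its probes, with adjusted p up to 0.561. Tpsg1 (-1.59 ± 0.11 (adjusted p = 0.0034)), Ccl9 (-1.51 ± 0.20 (adjusted p = 0.0287)), Hgfac (-1.35 ± 0.11 (adjusted p = 0.00356)) and Galnt12 (-1.14 ± 0.12 (adjusted p = 0.0105)) fell with them, and 8 of 43 goblet genes fell in all (adjusted over the list alone, 23 fell and 1 rose). Goblet cell genes had a median log2 of -0.38 (camera adjusted p = 3.49e-27; adjusted p = 0.0682 with an estimated correlation). Galnt12 was also the 1 of 48 mucin glycosylation genes to pass (1 adjusted over the list alone), and Nupr1 (-1.01 ± 0.12 (adjusted p = 0.0175)) the 1 of 26 Paneth genes (1 adjusted over the list alone). Mucin glycosylation genes had a median log2 of -0.11 (camera adjusted p = 3.63e-06; adjusted p = 0.424 with an estimated correlation). It was -0.066 without replicate 2. Paneth cell genes had a median log2 of -0.037 (camera adjusted p = 0.191; adjusted p = 0.957 with an estimated correlation). It was -0.022 without replicate 1 and -0.13 without replicate 2. Tff3 (-0.43 ± 0.10 (adjusted p = 0.303)), Foxa3 (-0.38 ± 0.12 (adjusted p = 0.503)), Clca1 (0.096 ± 0.36 (adjusted p = 1)), Lyz1 (0.026), Mmp7 (-0.42) and Ang4 (1.18) did not pass. Nor did Atoh1 (-0.12), Gfi1 (-0.15), Klf4 (-0.29), Dll1 (-0.02), Hes1 (0.019), Lgr5 (-0.028), Mki67 (0.18) or Chga (0.12). The kallikrein Klk1b3, a member of a large paralog family (-1.56 ± 0.21 (adjusted p = 0.0287)), and the protease inhibitor Serpina1d (-1.44 ± 0.18 (adjusted p = 0.0215)) fell, and so did the integrin Itga9 on its brightest probe (-1.60 ± 0.13 (adjusted p = 0.0034)), with its other probe in the opposite direction.

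Xist rose 16.2-fold in fetal colon (4.02 ± 0.39 (adjusted p = 0.00783)), the 1 of 4 sex-linked genes to pass (1 adjusted over the list alone). The wild type pools were low in Xist (log2 intensity 7.26 and 8.03) and carried Eif2s3y (11.13 and 11.06), while the KO pools carried both. The rise goes with the sex of the pools and cannot be read as an effect of Spdef loss. The value of Xist ran from 1.78 with the mean of all its probes to 7.57 with the series table, with adjusted p up to 0.0950, and its wild type signal was well above background on 3 of 4 arrays. Sex-linked genes had a median log2 of -0.38 (camera adjusted p = 0.867; adjusted p = 0.994 with an estimated correlation). Their mean was 0.67, of the opposite sign. Reg3b (1.22 ± 0.12 (adjusted p = 0.00872)), the 1 of 38 inflammation genes to rise (1 adjusted over the list alone), the zinc finger gene Zfp429 (1.20 ± 0.15 (adjusted p = 0.0215)), Xlr3c (1.17 ± 0.12 (adjusted p = 0.00878)), Pyy (0.82 ± 0.065 (adjusted p = 0.0034)) and Glo1 (0.72 ± 0.057 (adjusted p = 0.0034)) rose as well. Inflammation and antimicrobial genes had a median log2 of -0.023 (camera adjusted p = 0.918; adjusted p = 0.994 with an estimated correlation). Pyy was the 1 of 33 enteroendocrine genes to pass (5 rose adjusted over the list alone). Enteroendocrine cell genes had a median log2 of 0.14 (camera adjusted p = 5.13e-10; adjusted p = 0.313 with an estimated correlation). By limma 0 of 30 interferon and MHC class II genes passed (6 fell adjusted over the list alone). Interferon and MHC class II genes had a median log2 of -0.39 (camera adjusted p = 1.10e-11; adjusted p = 0.525 with an estimated correlation). It was -0.23 without replicate 1. Likewise 0 of 31 proliferation genes, 0 of 19 smooth muscle genes (1 rose adjusted over the list alone) and 0 of 21 neuron and glia genes passed by limma. Proliferation genes had a median log2 of 0.12 (camera adjusted p = 8.11e-07; adjusted p = 0.62 with an estimated correlation). Smooth muscle genes had a median log2 of 0.14 (camera adjusted p = 6.25e-05; adjusted p = 0.716 with an estimated correlation). It was 0.033 without replicate 1 (camera adjusted p = 0.552) and 0.26 without replicate 2. Enteric neuron and glia genes had a median log2 of 0.063 (camera adjusted p = 0.0133; adjusted p = 0.943 with an estimated correlation). It was 0.034 without replicate 1 (camera adjusted p = 0.497). Of 14 hepatocyte genes 2 fell, the paralogs Serpina1b and Serpina1c, chosen after their values were seen (3 adjusted over the list alone). Hepatocyte genes had a median log2 of -0.20 (camera adjusted p = 5.09e-05; adjusted p = 0.525 with an estimated correlation). It was -0.021 without replicate 1 (camera adjusted p = 0.408, direction turned) and -0.55 without replicate 2. In total 49 genes passed, 19 higher and 30 lower. Fetal colon pair 1 carried the tissue profile of small intestine (tissue score -2.12, against 1.64 for pair 2). The count was 29 without replicate 1 (20 higher, 9 lower), 25 without replicate 2 (5 higher, 20 lower), 28 without the slide of pair 1 and 132 when the group was fitted alone.

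**Figure D4:**
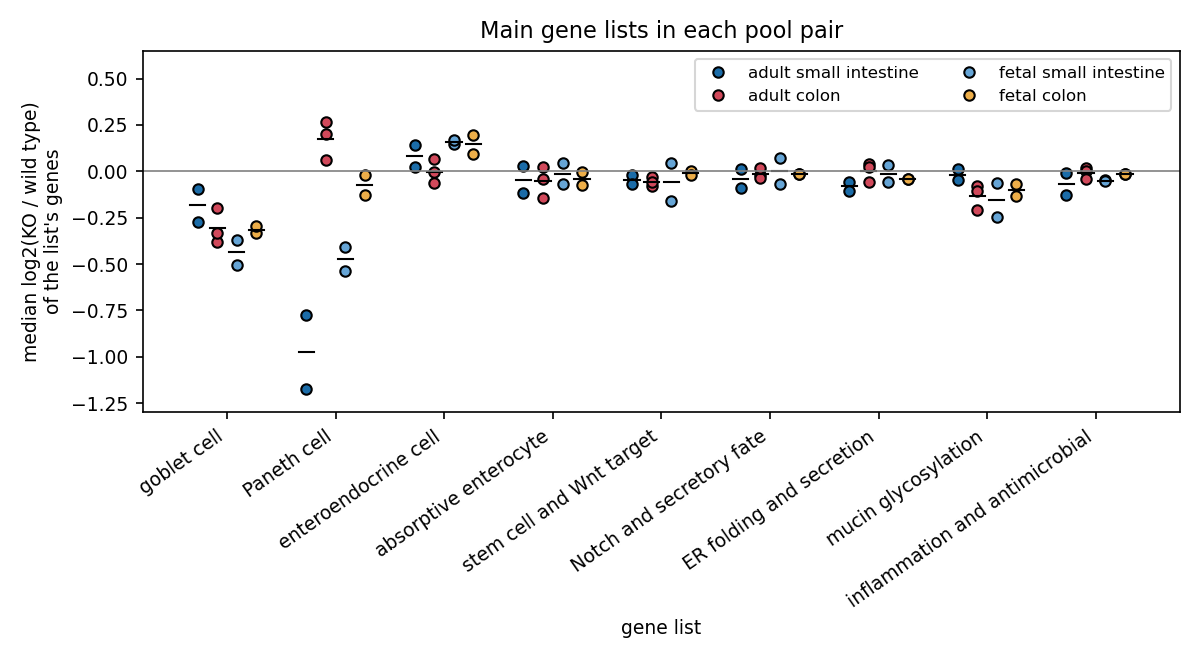
Median log2 ratio of KO over wild type over the genes of each main list (y axis, by list on the x axis); each point is 1 pool pair, colours are groups and short lines their means. Goblet cell medians lie below 0 in all 9 pairs, and Paneth cell medians fall to about -1.17 in adult small intestine and lie above 0 in the 3 adult colon pairs.

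Across the 96 list tests (24 lists in 4 groups), 37 passed with the preset correlation of 0.01 and 0 passed with an estimated one, as the p values given with each list show; goblet cells came closest, at 0.0682 in both fetal groups. By fry, which asks whether a list's genes move one way, 7 passed. Lists that did not pass in a group had adjusted p of 0.160 or more in adult small intestine, 0.157 in adult colon, 0.166 in fetal small intestine and 0.0548 in fetal colon. This covered the absorptive enterocyte, stem cell and Wnt target, Notch and secretory fate, T cell and NK cell, stomach, and fat and skeletal muscle lists in all 4 groups. In fetal small intestine and fetal colon the medians were -0.010 and -0.048 for enterocyte genes and -0.020 and -0.030 for stem cell genes. Both of these lists were among those that passed in a group when 1 replicate was left out. Leaving out 1 replicate brought 19 further lists in a group past the threshold, among them Notch and secretory fate in fetal small intestine without replicate 3 (adjusted p = 0.00667), T cell and NK cell in adult colon without replicate 2 (0.0117), fat and skeletal muscle in adult small intestine without replicate 2 (0.00174) and stomach in fetal colon without replicate 2 (0.0167). In 16 tests the median, the mean and the direction of the test differed in sign, and 0 of these passed (by camera).

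Calls overlapped between groups more often than independent calls would, tested with one-sided Fisher exact tests. All groups shared one estimate of the spread per gene, so their calls were not independent and these p values may be too small. Adult small intestine and adult colon shared 21 higher genes, including Glo1, Acer1 and Dnah8 (1.1 expected, adjusted p = 2.30e-23), and 13 lower genes, including Agr2, Galnt12 and Hgfac (2.25 expected, adjusted p = 2.61e-07). Lower genes shared by adult colon and fetal small intestine were 21, including Muc2, Spink4, Reg4 and Slc12a8 (2.98 expected, adjusted p = 6.30e-13), and 15 were shared with fetal colon (1.69 expected, adjusted p = 2.26e-11). Fetal small intestine and fetal colon shared 10 lower genes (0.093 expected, adjusted p = 3.86e-18) and 3 higher genes, Glo1, Pyy and Xlr3c (0.024 expected, adjusted p = 2.66e-06). Adult small intestine shared 11 lower genes with fetal small intestine (adjusted p = 1.10e-18) and 8 with fetal colon (adjusted p = 7.27e-15), and 2 higher genes with each, Glo1 and Pyy (adjusted p = 0.000704 and 0.000581). Higher genes of adult colon did not overlap those of fetal small intestine (2 shared, adjusted p = 0.213) or fetal colon (2 shared, adjusted p = 0.185) beyond chance.

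The KO effect was compared between stages to ask whether Spdef loss acts differently before and after birth. Effects were more positive in adults for Akr1c21 (difference 1.98 ± 0.18 (adjusted p = 0.00744)), ccdc198 (1.86 ± 0.16 (adjusted p = 0.00595)), Mmp7 (1.64 ± 0.15 (adjusted p = 0.00744)), the 14-3-3 protein gene Ywhaz (1.26 ± 0.082 (adjusted p = 0.00204)) and the copper chaperone Cox17 (0.99 ± 0.18 (adjusted p = 0.0485)). They were more negative in adults for Eif2s3y (by at least 2.08, adjusted p = 0.0125), Ddx3y (by at least 1.24, adjusted p = 0.0283), the X-linked Xlr4b (-1.13 ± 0.20 (adjusted p = 0.0466)) and Xlr3c (-0.98 ± 0.11 (adjusted p = 0.0125)), and Meg3, an imprinted noncoding RNA (-1.11 ± 0.14 (adjusted p = 0.0145)). The first pair are bounds, as their wild type signal in fetal small intestine was not above background. The Eif2s3y and Ddx3y differences go with the sex of those pools and are not shown to be effects of Spdef loss. Goblet cell genes fell less in adults (median difference 0.27, camera adjusted p = 1.83e-06, and adjusted p = 0.292 with an estimated correlation), and B and plasma cell genes were relatively higher (median difference 0.37, camera adjusted p = 2.14e-06, and adjusted p = 0.491 with an estimated correlation). In total 184 genes passed, 90 higher and 94 lower in adults. The only slide with both stages held adult colon pair 3 and fetal colon pair 2; its differences were 4.62 for Akr1c21, 3.72 for Mmp7, 1.36 for Ywhaz, 0.84 for Cox17, -0.52 for Xlr4b, -0.56 for Xlr3c and -1.95 for Meg3. With colon pools only, that slide could not show the differences of ccdc198, Eif2s3y and Ddx3y, which came from fetal small intestine (0.046, 0.66 and 0.48 within it). The count fell to 1 without the slide of fetal small intestine pair 3 and fetal colon pair 1, was 0 with median centring (537 at an unadjusted p under 0.05, limma), and was 114 and 94 without adult small intestine replicates 1 and 2, 289 and 34 without fetal small intestine replicates 1-2 and 3, 11 without adult colon replicate 1, and 23 and 14 without fetal colon replicates 1 and 2.

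The KO effect was also compared between small intestine and colon as labelled. Paneth cell genes were relatively lower in small intestine, with 6 of 26 past the threshold (median difference -1.01, camera adjusted p = 7.71e-23, and adjusted p = 0.133 with an estimated correlation), among them Mmp7 (-2.07 ± 0.15 (adjusted p = 0.00344)) and the alpha-defensin Defa23 (by at least 1.12, adjusted p = 0.0388). Akr1c21 (-2.09 ± 0.18 (adjusted p = 0.00514)), ccdc198 (-2.26 ± 0.16 (adjusted p = 0.00344)) and Xist (-2.77 ± 0.37 (adjusted p = 0.0404)) were lower too. More positive in small intestine were Eif2s3y (by at least 2.05, adjusted p = 0.0161), Ddx3y (by at least 1.33, adjusted p = 0.0454), Itga9 (1.33 ± 0.12 (adjusted p = 0.0054)), the collagen gene Col8a1 (0.73 ± 0.082 (adjusted p = 0.0181)) and the vesicle tethering factor Vps39 (0.63 ± 0.049 (adjusted p = 0.00344)). Goblet cell genes showed no such shift (median difference -0.017, camera adjusted p = 0.946, and adjusted p = 0.986 with an estimated correlation), while proliferation genes were relatively lower in small intestine (median difference -0.26, camera adjusted p = 9.16e-21, and adjusted p = 0.307 with an estimated correlation; the median was -0.17 without fetal small intestine replicate 1-2). In total 29 genes passed, 8 higher and 21 lower. Of these, Eif2s3y, Ddx3y and Xist differed with the sex of the fetal pools, which cannot be separated here from an effect of Spdef loss. Within the slide of adult small intestine pair 2 and adult colon pair 2 the differences were -3.47 for Mmp7, -4.06 for Akr1c21, -1.77 for Defa23, 0.38 for Itga9, 1.17 for Col8a1 and 0.19 for Vps39. It could not show the differences that came from fetal pools (Eif2s3y -0.28, Ddx3y -0.15, Xist 0.31, ccdc198 0.51). Within the slide of fetal small intestine pair 3 and fetal colon pair 1 they were -0.33, 0.33, -1.08, 2.49, 0.22, 1.15, 3.93, 3.09, -4.57 and -4.36 in the same order of genes. For Defa23 in the adult slide and Eif2s3y and Ddx3y in the fetal slide these are fitted values with a wild type signal at background, which give the direction only. The count was 4 without that slide, 13 without adult colon replicate 1 and 17 without fetal colon replicate 1.

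Wild type pools were compared between stages for the background expression of these genes. In small intestine, adult pools were higher in the alpha-defensins Defa31 (8.79 ± 0.38 (adjusted p = 6.06e-05)) and Defa21 (8.31 ± 0.62 (adjusted p = 0.000522)), the brush border enzyme Sis (7.55 ± 0.63 (adjusted p = 0.000811)), the antimicrobial lectin Reg3a (7.40 ± 1.29 (adjusted p = 0.0169)) and Prm1 (7.79 ± 0.23 (adjusted p = 1.84e-05); 3.87 with the mean of all its probes). Fetal pools were higher in the imprinted genes H19 (-8.55 ± 0.68 (adjusted p = 0.00066)) and Dlk1 (-6.24 ± 0.69 (adjusted p = 0.00288)), the water channel Aqp8 (-6.88 ± 0.69 (adjusted p = 0.00182)), the folate receptor Folr1 (-6.05 ± 0.80 (adjusted p = 0.00575)) and Mamdc4 (-6.04 ± 0.84 (adjusted p = 0.00732)). In all 1441 genes passed, 815 higher in adults and 626 lower. The count was 277 and 283 without adult small intestine replicates 1 and 2, 679 and 362 without fetal small intestine replicates 1-2 and 3, and 315 with the replicate number as a block; no slide held adult and fetal small intestine, so slide and stage could not be told apart.

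In wild type colon, adult pools were higher in the goblet cell product Retnlb (7.30 ± 0.92 (adjusted p = 0.00515)), the immunoglobulin genes Jchain (at least 7.22, adjusted p = 4.34e-05) and Iglv1 (7.19 ± 0.56 (adjusted p = 0.00082); 4.63 with the mean of all its probes), and the carbonic anhydrases Car1 (6.97 ± 1.27 (adjusted p = 0.0194)) and Car4 (6.46 ± 0.17 (adjusted p = 1.84e-05)). Fetal pools were higher in H19 (-8.66 ± 0.62 (adjusted p = 0.000494)), Igf2 (-7.27 ± 0.25 (adjusted p = 3.92e-05)), Afp, the fetal serum protein (-8.26 ± 0.75 (adjusted p = 0.00146)), Meltf (-8.45 ± 0.71 (adjusted p = 0.0011)) and the apolipoprotein Apoa1 (by at least 7.09, adjusted p = 0.0379). Without fetal colon replicate 1, the pair with the tissue profile of small intestine, the fitted difference of Apoa1 was -4.64. On the slide that held both stages it was -4.76. The bound of 7.09 thus holds only for the group as labelled and rests on that pair. In all 1489 genes passed, 1004 higher in adults and 485 lower. On the slide that held adult colon pair 3 and fetal colon pair 2 all 10 differences kept their sign, with -7.67 for H19, 5.50 for Car1 and -7.02 for Igf2. The count was 979 and 591 without adult colon replicates 2 and 3 and 636 and 753 without fetal colon replicates 1 and 2. The fetal groups entered both comparisons as labelled.

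**Figure D5:**
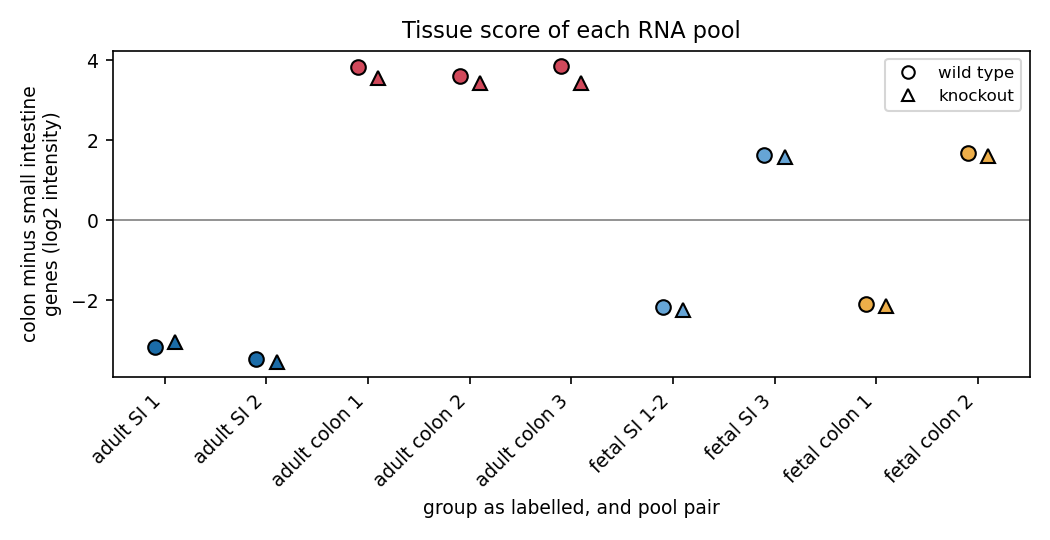
Mean log2 intensity of 192 colon genes minus that of 339 small intestine genes (y axis; genes chosen on adult wild type pools) for each pool (x axis, groups as labelled); circles are wild type and triangles KO pools. Fetal small intestine pair 3 scores 1.61 and fetal colon pair 1 scores -2.12 on average, each on the side of the other tissue.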

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

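The tests of exchanged tissue labels and of mixing were set before their results were seen; the slide test and the counts over other splits were chosen afterwards. The results below were set apart because the KO effect differed between stages or tissues by limma's test of the difference itself. By stage (adult minus fetal), the differences were 1.98 for Akr1c21, 1.86 for ccdc198, 1.64 for Mmp7, 1.26 for Ywhaz and 0.99 for Cox17. They were -2.12 for Eif2s3y, -1.27 for Ddx3y, -1.13 for Xlr4b, -1.11 for Meg3 and -0.98 for Xlr3c. By tissue (small intestine minus colon), they were 2.09 for Eif2s3y, 1.36 for Ddx3y, 1.33 for Itga9, 0.73 for Col8a1 and 0.63 for Vps39, and -2.77 for Xist, -2.26 for ccdc198, -2.09 for Akr1c21, -2.07 for Mmp7 and -1.17 for Defa23. The fitted values of Eif2s3y and Ddx3y rest on a wild type signal at background in fetal small intestine, and that of Defa23 on one in adult colon. As bounds, Eif2s3y and Ddx3y differed by at least 2.08 and 1.24 by stage and 2.05 and 1.33 by tissue, and Defa23 by at least 1.12. The differences of Eif2s3y, Ddx3y and Xist go with the sex of the fetal pools, which could not be separated from genotype there.

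Behind these differences, Akr1c21 had a log2 of 4.29 in adult colon and between 0.04 and 0.22 in the other 3 groups. Mmp7 had 2.91 in adult colon and -0.85, -0.80 and -0.42 in adult small intestine, fetal small intestine and fetal colon. The ccdc198 value was -4.42 in fetal small intestine, with -4.52 in pair 1-2 and -4.32 in pair 3, and between -0.33 and 0.07 elsewhere. Meg3 (-1.47) and Col8a1 (-1.25) fell in adult colon, and Vps39 fell in 3 groups (-0.74 in adult small intestine, -0.94 in adult colon, -0.58 in fetal colon) and rose in fetal small intestine (0.49). Itga9 had -1.60 in fetal colon and 0.68 in fetal small intestine.

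For the stage difference, 1 of 60 exchanges of the stage labels within tissues, the real one, gave as many genes (184, against 19 for the highest other). That share is under 0.05, but the test was chosen after the counts were seen and does not exclude chance labelling. For the tissue difference, 2 of 60 exchanges of the tissue labels gave 29 genes, the real one and another (highest other 29). The share is under 0.05, but that other split placed adult small intestine pair 2 and adult colon pair 2, which shared a slide, on one side. With slide as a random block the count was 35, and with the tissue labels of fetal small intestine pair 3 and fetal colon pair 1 exchanged it was 14.

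Fetal small intestine pair 3 and fetal colon pair 1, which shared a slide, carried each other's tissue profile, and the tissue difference uses them as labelled. Hoxb13, a gene of the hindgut, had wild type log2 intensities of 11.64 in fetal small intestine pair 3 and 6.99 in fetal colon pair 1, against 7.05 in fetal small intestine pair 1-2 and 11.15 in fetal colon pair 2. A shift of both pairs by the slide is argued against, since their scores moved in opposite directions by nearly the same amount (ratio -0.985), and so is a partial mixture, since neither lay outside the range of the other tissue by more than 0.0081 of the gap between tissues. An exchange of tissue labels between the pairs remains a candidate explanation: their gap was 0.971 of that between the other fetal pools of the tissues. Some KO effects and sex-linked genes went with the labels but do not settle it, since littermate sets may have given both tissues: ccdc198 was lower in fetal small intestine pair 3 than in fetal colon pair 1 (difference -4.36), the Paneth cell medians were -0.41 and -0.13, both pairs labelled fetal small intestine had wild type pools without Eif2s3y signal (7.13 and 6.94), and both labelled fetal colon had wild type pools with it (11.13 and 11.06).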

How the results depend on the processing

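Alternatives with fetal small intestine pairs 1 and 2 separate, without one slide, or without sex chromosomes were chosen after the data were seen. Spdef stayed below 0 in every group under every alternative, and of the 144 named gene values past the threshold 0 turned direction. The genes named for the largest change in a group had the same sign in every replicate by rule, so leaving out a replicate could not turn them. The trended, robust prior and the omission of genes on chromosomes X and Y left the log2 values unchanged and could not turn a direction either. Many named gene values lost their call: of 3620 values under the alternatives 2971 kept direction and side of the threshold, 571 kept their direction but no longer passed, 40 came to pass, and 38 not past it as reported changed sign. Of the 144 calls, 79 were lost with median centring, 87 with the trended, robust prior, 50 with only the groups compared and 63 without the slide. When 1 replicate was left out, 187 of 707 values, called or not as reported, lost a call. Among those past it in the fewest alternatives were Cbr1, Nt5e and Cxcl9 (7 of 17) and Defa21 (8 of 17) in adult small intestine, Ang2 and Ang6 (8 of 18) in adult colon, Xlr5a (7 of 16), Ccl6 (7 of 17) and Kdelr3 (8 of 17) in fetal small intestine, Xist in the mean (9 of 22), and Cox17 (9 of 24) and Xlr4b (8 of 23) in adult minus fetal. Sizes moved too: with the mean of all probes log2 values shrank to -0.61 and -0.58 for Muc2 in fetal small intestine and fetal colon, 1.78 for Xist and -0.77 for Itga9 in fetal colon, 0.95 for Rrp7a in fetal small intestine, -0.86 for Prm1 in adult small intestine, and -0.12, -0.16 and -0.082 for Maf, Rgmb and Cplx2 in adult colon. They were 0.41 for Nt5e in adult small intestine, 1.63, -1.04, -0.30 and -0.19 for H2-Bl, Rap1gap, Gfpt1 and St6galnac2 in adult colon, 0.39 for Xist in the mean, 0.81, 0.49, -0.73 and -0.70 for Ywhaz, Cox17, Xlr4b and Meg3 in adult minus fetal, 0.70, 0.36 and -1.37 for Itga9, Vps39 and Xist in small intestine minus colon, and 3.87 and 4.63 for Prm1 and Iglv1 in wild type. With processed signals they grew to 7.56 for Xist in fetal colon, and to 2.77 for Rbm45 and -1.12 for S100a8 in fetal small intestine, 2.26 for Zfp429 and -2.03 for Hgfac in fetal colon, and -4.11 for Spdef and 1.82 for Akr1c21 in the mean. Counts are given in the order adult small intestine, adult colon, fetal small intestine, fetal colon, mean of the 4, adult minus fetal, small intestine minus colon, wild type small intestine and wild type colon, where they differed from the reported ones by more than 1.5 times. With median centring all 9 counts fell, to 20, 57, 10, 5, 74, 0, 7, 311 and 955. With every array as an observation and the pair as a random block they rose to 502, 3048, 347, 197, 1213, 1312 and 247 for the 7 KO contrasts. That fit enters each dye swap as a measurement of its own, correlated within its pair. With a trended, robust prior they were 13, 956, 31, 15, 0, 20 and 2 for the KO contrasts (2556 genes at an unadjusted p under 0.05 for the mean). With processed signals they were 125 for adult small intestine, 985 for adult colon, 87 for fetal colon, 3286 and 3305 for the wild type comparisons. Groups fitted alone gave 0 (1831 at an unadjusted p under 0.05), 160, 28 and 132 for the 4 groups and 457 for wild type colon. The series table gave 765 for adult colon and 90 for fetal colon, and no background subtraction 106 for fetal colon. The replicate number as a block gave 38 for adult small intestine, 115 for adult minus fetal, 315 and 531 for wild type. The strict filter gave 879 for wild type small intestine and 24 list tests. Separate fetal pairs gave 133 for adult small intestine, 343 for fetal small intestine, 746, 666 and 65 for the mean and the differences, and 2796 and 2283 for wild type. Without the slide of fetal small intestine pair 3 and fetal colon pair 1 they were 27, 779, 14, 28, 45, 1 and 4 for the KO contrasts. Leaving out 1 replicate gave 47 to 84 for adult small intestine, 317 to 958 for adult colon, 31 to 31 for fetal small intestine, 25 to 29 for fetal colon, 129 to 323 for the mean, 11 to 289 for adult minus fetal, 13 to 33 for small intestine minus colon, and 277 to 679 and 591 to 1959 for wild type small intestine and colon. Slide as a fixed block left no residual degrees of freedom and was not run; as a random block it changed no count by more than 1.5 times.

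Scaling also moved directions. Splits into higher and lower genes were 32 and 93 with processed signals, 0 and 20 with median centring and 21 and 68 with the series table for adult small intestine. With median centring they were 11 and 46 for adult colon, 0 and 5 for fetal colon, 7 and 67 for the mean, 1 and 6 for small intestine minus colon and 875 and 80 for wild type colon. With processed signals they were 63 and 122 for adult minus fetal, 14 and 20 for small intestine minus colon and 1792 and 1513 for wild type colon. Median centring moved the median of all genes to -0.14 in fetal colon, -0.20 in wild type small intestine and 0.33 in wild type colon, and processed signals to -0.13 in wild type colon. Of 37 list tests, 0 passed with an estimated correlation by camera and 7 by fry. Lists that turned direction were pancreas in adult small intestine without replicate 2 (adjusted p = 5.03e-06) and proliferation in fetal small intestine without replicate 1-2 (adjusted p = 0.0226). Interferon and MHC class II genes in adult colon turned without replicate 2 (adjusted p = 0.898), and hepatocyte genes in fetal colon without replicate 1 (0.408) and without the slide of that pair (0.411). Over the omissions of single replicates the adjusted p of these lists ran from 6.02e-15 to 0.0299 for pancreas, from 2.11e-11 to 0.0442 for proliferation, from 1.83e-05 to 0.898 for interferon and MHC class II and from 3.45e-18 to 0.408 for hepatocyte. Overlaps past the threshold fell from 10 to 6 of 12 with median centring. Probes near background limit what small changes can be seen: between 39.7% and 71.6% were well above it in a channel.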

Other observations

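All tests in this part were chosen after the results were seen. Sex-linked transcripts set the fetal groups apart. In wild type pools Xist was at 11.71 and 13.00 (log2 intensity) in the pairs labelled fetal small intestine and at 7.26 and 8.03 in those labelled fetal colon, and Eif2s3y went the other way. KO pools of both groups carried both transcripts, with Xist from 10.10 to 12.63 and Eif2s3y from 10.31 to 11.10. In the adult pools both transcripts were present in both genotypes, but not always at equal levels. In the adult small intestine pairs the log2 ratio was -0.30 and 1.28 for Xist and -0.13 and -1.10 for Eif2s3y. In the adult colon pairs it was 0.85, 0.97 and 0.13 for Xist and -0.48, -0.82 and -0.09 for Eif2s3y. Sex make-up may thus have differed by degree between genotypes in some adult pairs too. The fetal pools clearly differed in sex make-up between genotypes, and their differences in Eif2s3y, Ddx3y and Xist cannot be assigned to loss of Spdef. Without genes on chromosomes X and Y, 68 genes passed in fetal small intestine and 47 in fetal colon.

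Genes past the threshold in the mean of the 4 groups gathered on chromosome 17, where Spdef lies. Within 10 Mb of Spdef 31 of 422 genes passed (7.35%), against 271 of 16541 elsewhere (1.64%; one-sided Fisher exact adjusted p = 1.84e-10), 14 of them higher and 17 lower. The excess passed in adult small intestine (8 genes, ratio of shares 5.31, adjusted p = 0.00062) and adult colon (67 genes, ratio 1.69, adjusted p = 7.78e-05). It did not pass in fetal small intestine (2 genes, ratio 1.07, adjusted p = 0.764) or fetal colon (2 genes, ratio 1.67, adjusted p = 0.647). Few genes were called in the fetal groups, and the excess was not compared between groups. Among the genes were Glo1 (1.02), Tpsg1 (-1.37), H2-Bl (1.94), Zfp945 (-1.11, with 0.28 and 0.21 on its other probes), Gfer (-0.35), Fgd2 (0.43), Dnah8 (0.41), H2-T22 (-0.42) and H2-M3 (-0.33). On the whole chromosome 53 of 832 genes passed, from 5.37 to 56.6 Mb. The excess was not centred on Spdef. Of 210 bins of 10 Mb across the genome, 0 to 10 Mb of chromosome 17 had the highest share (7 of 35 genes, 20%). The bin that holds Spdef (20 to 30 Mb) ranked 3 (20 of 203, 9.85%). Shares were 8.47% at 10 to 20 Mb, 4.93% at 30 to 40 Mb and 6.19% at 40 to 50 Mb. Genes of chromosome 17 beyond 10 Mb from Spdef count as elsewhere above.

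An effect on the closest neighbours alone is argued against, as the share of passing genes between 1 and 10 Mb from Spdef was 4.72 times that elsewhere. A candidate explanation is a stretch of donor-strain chromosome that stayed linked to the targeted allele, which would act in every tissue: of adult colon calls, 35 of 67 within 10 Mb went the same way in all 3 other groups (52.2%), against 355 of 1550 elsewhere (22.9%), a ratio of 2.28 (one-sided Fisher exact p = 3.52e-07). Whether sequence differences under single probes contribute cannot be told apart, since 58.8% of 17 other probes of these genes shared the direction, 10 of them. Tpsg1, which fell in all 4 groups, and Glo1 may therefore owe part of their change to linkage, which these arrays cannot separate from loss of Spdef.

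Pancreas genes differed between the channels in adult pairs. Their median log2 ratio was 0.87 and -3.12 in the adult small intestine pairs and -2.32, -0.01 and -2.83 in the adult colon pairs. A loss in all adult KO pools is argued against by the pair with a median of 0.87, where 0 of 20 genes lay below 0. Pancreas carried along in the dissection of some pools is a candidate explanation, since pools of one genotype and tissue differed in the median level by up to 7.69 on the log2 scale (wild type colon, from 7.27 to 14.96).

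For adult colon, 4 sign patterns of the 3 pairs are too few to give a share under 0.05; 1 of them, the real one, gave 1630 genes, and the highest other gave 0. For the mean of the 4 groups, 1 of 100 sign patterns of the 9 pairs, the real one, gave as many genes (305, against 184 for the highest other). That share is under 0.05, which makes chance labelling less likely there but does not exclude it.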
